A study of Arabidopsis thaliana with 16 samples.

How the data were processed

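Gene expression was measured on Affymetrix arrays in whole wild-type Arabidopsis seedlings (ecotype Col) grown in liquid medium for 12 days. Per the labels' protocols, seedlings were moved to darkness for 1 h, pretreated for 30 min with hydrogen peroxide (H2O2) at 0, 1, 5, 25, 50 or 100 mM, and then given 1 µM epi-brassinolide (BL), a steroid hormone that promotes growth, or the same volume of its ethanol solvent. The hormone acted for 1 h in darkness with the H2O2 still present. Total RNA was extracted with TRIzol and labelled with biotin by the 3' one-cycle protocol. The 16 arrays form 12 groups: 3 arrays each for BL and solvent at 0 mM H2O2, and 1 array for every combination of a higher dose with BL or solvent. The labels number the replicates but do not say whether they are separate cultures.

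The deposited values are one log2 signal per probe set and array, made with GCRMA per the submitters' processing notes, which give neither its version nor its settings. GCRMA corrects the background by probe sequence, normalizes across arrays and summarizes each probe set. The log2 scale was read from the values. On every array the lowest value was 2.12, the medians lay between 5.50 and 5.71 and the highest values between 15.2 and 15.5. These values were used without further scaling. No 2 columns held identical values, and all deposited columns were used. Arrays have no read depth, and both their number and the spread between them limit the precision. The genome build behind the array annotation is not given in the sources used here.

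The table held 22810 entries, of which 64 were control probe sets, leaving 22746. A probe set entered the tests if its value was at least 5 on at least 2 of the 16 arrays, which kept 13140. The platform annotation gave 13513 probe sets 1 gene symbol, 503 several and 8730 none. Among those kept the numbers were 7040, 297 and 5803, and the last are called unnamed here. Of the probe sets with 1 gene, 13436 matched a RefSeq gene table of the TAIR10.1 assembly, used for names only, and 77 did not. What a gene's product is was added as general background, since the tables hold no such descriptions. A gene was represented by its probe set with 1 gene and the highest mean over the arrays.

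Tests were made with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with statmod 1.5.0, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. BL was compared with solvent on the 6 arrays at 0 mM. Each dose was compared with 0 mM in a fit to all 16 arrays with dose as a factor and BL as an additive term, so that 2 arrays per dose met 6 at 0 mM with 9 residual degrees of freedom. Slopes over log2(1 + dose in mM) were fitted with and without BL in one model, as was their difference, with 12 residual degrees of freedom. They are printed as the fitted log2 change over the whole range of doses. Another model, with 8 residual degrees of freedom, estimated the BL response at 0 mM and as a mean over the 5 higher doses, and the difference of both. These 11 comparisons, the filter, the threshold, the gene lists and the rule for naming genes were fixed before the data were examined. A further slope over the 10 arrays from 1 to 100 mM, with BL as an additive term and 7 residual degrees of freedom, was added after the data had shown that the 0 mM arrays stand apart. Above 0 mM no combination of dose and BL state has a replicate, so the p-values measure the spread between these arrays and not between repeated experiments.

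The fixed lists numbered 25 with 390 genes. The annotation gave 66 of them a probe set of their own, of which 53 passed the filter, and gave 324 none. The 9 lists with at least 3 tested members were heat shock proteins and factors, oxidative stress transcription factors, detoxification, antioxidant enzymes, abscisic acid and dehydration, cell wall loosening, gibberellin, photosynthesis and reference genes. Lists of brassinosteroid synthesis, signalling and target genes had too few members with a probe set of their own in the annotation that passed the filter. Since the annotation left 8730 probe sets without a gene symbol, this does not mean that the array lacks these genes. Another 8 lists were added after the data were seen: glutathione S-transferases, UDP-glycosyltransferases, WRKY factors, cytochromes P450, expansins, xyloglucan endotransglucosylases, and the plastid-encoded and mitochondria-encoded genes. All 11 tested cytochrome P450 members are CYP71B genes, so that list does not stand for the whole family. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the residuals, adjusted over the lists within a comparison, separately for fixed and added lists. Over the 12 comparisons the fixed lists gave 108 tests, of which 21 were called at the preset correlation and 0 with the estimated one.

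In each comparison the rule names the 10 largest called rises and the 10 largest called falls among probe sets with 1 gene that moved the same way in every replicate or pair, up to 4 called members of every list, and 17 fixed hormone and stress marker genes whatever their p. Among the comparisons of single doses it gives the rises and falls for 100 mM only. Its wording leaves open whether list members are named at the lower doses, and naming them there was chosen after their values were seen. For none of the 17 marker genes (0 of 17) did the files give a probe set with that gene alone, so they are not analysed here. From the genes the rule gives, the text prints a selection.

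All fits were tested on simulated data with the real spread per probe set, in which 200 of the 13140 probe sets changed by a log2 of 1 or 2, 100 at each size. A change of 2 was recovered for 70% of probe sets in the BL comparison at 0 mM, 85% at 1 mM H2O2 and 87% at 100 mM. A change of 1 was recovered for 16%, 53% and 48%. Between 2 and 13 of 12940 unchanged probe sets were called in any of the 12 comparisons. The noise was normal, independent between probe sets and equal on all arrays. The simulated data therefore hold no array that stands apart from its group, and these figures hold for that setting only. Alternatives changed the filter (none, or a minimum of 7), the scaling (quantile, or centring on medians), the eBayes prior, a minimum change, the dose scale, the arrays in the fit and the test, and left out every array in turn. For gene lists the alternatives were the estimated correlation, quantile scaling, no filter and the arrays left out, and for the added lists and the added slope they were run only after the result was seen. The closing section gives their effect.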

Results

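The seedlings met hydrogen peroxide (H2O2), an oxidative stress, and then the brassinosteroid BL, so the arrays hold both treatments and their combination. At 0 mM there were 3 arrays with BL and 3 with its solvent, called solvent controls 1 to 3, and each higher dose had 1 array with BL and 1 with solvent. Across the probe sets kept, the pair of arrays at one dose above 0 mM had a Pearson correlation between 0.988 and 0.995, with or without BL. The 0 mM arrays other than solvent control 3 correlated with one another at 0.958 to 0.990 and with the H2O2 arrays at 0.890 to 0.935. Solvent control 3 stood apart, with correlations of 0.816 to 0.907 to its own group and the BL arrays at 0 mM and 0.857 to 0.890 to the H2O2 arrays. Solvent control 1 lay partway towards it. It correlated with solvent control 3 at 0.907, while solvent control 2 and the BL arrays at 0 mM did so at only 0.8163 to 0.8225. These correlations are over probe sets, which are not independent replicates. The first principal component held 45.7% of the variance, the second 27.1% and the third 12.5%.

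**Figure D1:**
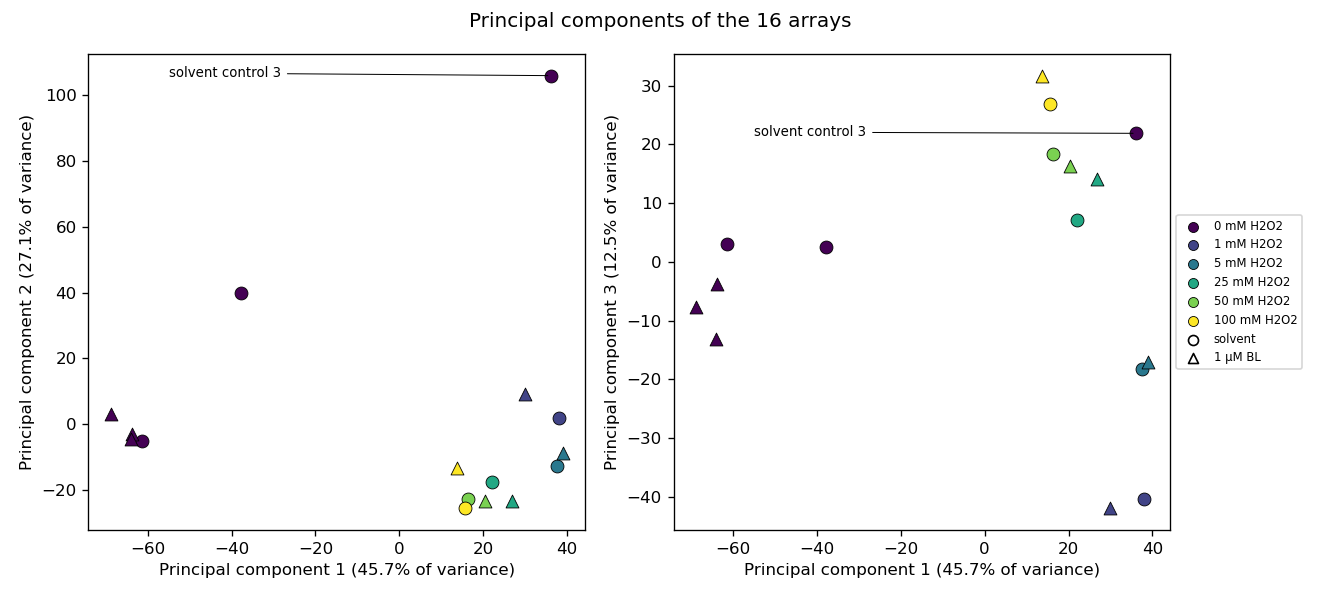
The 16 arrays on principal component 1 (45.7% of the variance, x axes) against component 2 (27.1%, left y axis) and component 3 (12.5%, right y axis), coloured by H2O2 dose, with circles for solvent and triangles for BL. The 5 other arrays at 0 mM lie at negative values of component 1, while solvent control 3 lies at 36.2, among the H2O2 arrays. On component 2 it lies at 106, above every other array, and on component 3 at 21.9. Solvent control 1, at -37.7 on component 1 and 39.9 on component 2, lies nearer to it than the other 0 mM arrays do.

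H2O2 at 1 mM raised small heat shock protein genes, CML37, and single genes of detoxification enzymes such as GSTU25. The glutathione S-transferase gene GSTU25 went from 2.32 ± 0.21 (SD, n = 6) at 0 mM, close to the lowest value on the arrays, to a mean of 9.09 at 1 mM. The heat shock genes HSP26.5, HSP17.6C and HSP22, and FES1A, whose product works with heat shock proteins, rose as well. CML37 encodes a calmodulin-like protein, and the dehydrin gene LTI30 and the UDP-glycosyltransferase genes UGT73B4, UGT73B5 and GT72B1 rose with it. The transcription factor genes ZAT10 and WRKY6, and the unfolded protein response gene BZIP60, were also called.

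The question of this comparison was what the lowest dose does to expression. GSTU25 changed by a log2 of 6.77 (SE 0.16, limma adjusted p = 1.01e-09), a 109-fold rise that its 0 mM level near the floor of 2.12 leaves uncertain in size. HSP26.5 rose by 5.91 (SE 0.66, adjusted p = 0.00015), HSP17.6C by 4.97 and HSP22 by 4.91, and FES1A by 4.47 (SE 0.36, adjusted p = 1.39e-05). CML37 rose by 5.05 (SE 0.17, adjusted p = 2.00e-08), also from near the floor, and LTI30 by 3.65 (SE 0.25, adjusted p = 3.67e-06). UGT73B4 rose by 5.56 (SE 0.52, adjusted p = 4.51e-05), UGT73B5 by 5.55 and GT72B1 by 4.93 (SE 0.20, adjusted p = 6.19e-08). All of these calls held when any single array was left out. ZAT10 rose by 4.03 (adjusted p = 0.00817), but solvent control 3 already held it at 11.07 against a 0 mM mean of 7.87 ± 1.84 (SD, n = 6). WRKY6 rose by 1.92 (adjusted p = 0.0149), and both calls were lost without the 1 mM solvent array (adjusted p = 0.0754 and 0.107) or the 1 mM BL array (0.108 and 0.158). BZIP60 rose by 1.32 (adjusted p = 0.032), a call also lost without solvent control 1, any BL array at 0 mM, or either 1 mM array. The reference gene TIP41 fell by 0.46 (adjusted p = 0.00765), a call lost without the 1 mM solvent array (adjusted p = 0.112) or the 1 mM BL array (0.0769).

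All 10 tested members of the heat shock list were called up at 1 mM, with a median log2 change of 3.73 (camera adjusted p = 2.73e-11, and 0.176 with an estimated correlation). Adjusted over the list alone, 10 were called. The list averaged 7.47 ± 1.00 (SD, n = 3) in solvent and 8.86 ± 0.26 in BL at 0 mM, and 11.9 on both 1 mM arrays. Solvent control 3 lay at 8.62, the other solvent controls at 6.99 and 6.79. The detoxification list of GSTU25, DTX3 and UPOX had a median of 0.64 and a mean of 2.23 (adjusted p = 0.0278, and 0.176 with an estimated correlation), with 1 member called, or 2 adjusted over the list alone. The abscisic acid list had a median of 0.81 (adjusted p = 0.0278, and 0.189 with an estimated correlation) with 1 of 3 called, and both lists reached only 0.0803 without solvent control 3. Without the 1 mM solvent array the abscisic acid list reached 0.0697. The oxidative stress transcription factors, WRKY53, ZAT10 and WRKY6, had a median of 1.92 with 2 of 3 called (adjusted p = 0.0609, and 0.435 with an estimated correlation), reaching 0.0377 without solvent control 1. Photosynthesis genes had a median of 0.19 (adjusted p = 0.337), antioxidant enzymes 0.03 (0.797), cell wall loosening genes -0.07 (0.817), gibberellin genes 0.24 (0.649, with GID1B called up) and reference genes -0.25 (0.301).

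Of the families added after the data were seen, 1 was called at this dose. Since they were chosen after the same data were seen, their p-values at any dose are no independent support. Of 28 UDP-glycosyltransferase genes, 7 were called up and 1 down at 1 mM, with a median log2 change of 0.32 (adjusted p = 0.000109, and 0.00675 with an estimated correlation), and the list call held without any single array. Glutathione S-transferases had a median of -0.09 but a mean of 0.96, driven by GSTU25 (adjusted p = 0.262), and a median of 0.17 without the 1 mM BL array (0.0316). WRKY factors had a median of 0.29 (adjusted p = 0.590), the 11 cytochromes P450, all CYP71B genes, 0.10 (0.590), expansins -0.45 (0.590) and xyloglucan endotransglucosylases -0.19 (0.722). Plastid-encoded genes had a median of 0.11 (0.380, and 0.0316 without the 1 mM BL array) and mitochondria-encoded genes -0.34 (0.722), with 0 of 69 and 0 of 11 called by limma. Among all 13140 probe sets, 2639 were called for H2O2 1 mM against 0 mM, 1262 up and 1377 down. The count was 1031 with a log2 change of at least 1, 4755 with the first replicates only, 5981 without solvent control 3, 676 without the 1 mM solvent array and 704 without the 1 mM BL array.

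At 5 mM GSTU25, CML37 and heat shock genes were raised again. GSTU25 rose by 6.82 (SE 0.16, adjusted p = 5.41e-10), CML37 by 5.72, HSP26.5 by 5.05, UGT73B4 by 5.39, GT72B1 by 4.95 and FES1A by 3.44. The plastid photosystem gene psaA fell by 2.22 (SE 0.36, adjusted p = 0.00159) and the expansin gene EXPA16 fell too, while LTI30 rose by 2.39. These calls held without any single array. Of 69 plastid-encoded genes, 12 were called up and 7 down, with a median of -0.16 (camera adjusted p = 0.875), or of 0.11 without the 5 mM BL array (0.0192). Of these, rps14 rose by 3.27 (adjusted p = 0.00312), petD by 2.58 and petN by 1.95. Without the 5 mM solvent array the adjusted p was 0.0538 for rps14 and 0.0770 for petN, and without the 5 mM BL array 0.0715 for petD and 0.102 for petN. Of 10 heat shock genes, 9 were called up, also when adjusted over the list alone, with a median of 2.76 (camera adjusted p = 1.06e-07, and 0.248 with an estimated correlation). UDP-glycosyltransferases, a list added after the data were seen, had 10 of 28 up (adjusted p = 0.00139, and 0.0176 with an estimated correlation). Their median was 0.28, and 0.18 without the 5 mM BL array. The stromal ascorbate peroxidase gene SAPX fell by 0.69 (adjusted p = 0.0203), a call lost without the 5 mM solvent array (0.261) or the 5 mM BL array (0.0528). For H2O2 5 mM against 0 mM, 1281 probe sets were called up and 1769 down, 3050 together, with 1190 at a log2 change of at least 1 and 5186 with the first replicates only. Without solvent control 3 the count was 5984, without the 5 mM solvent array 965 and without the 5 mM BL array 879.

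At 25 and 50 mM, single plastid-encoded genes and stress genes were raised. The ribosomal protein gene rps14 rose by 4.66 (SE 0.59, adjusted p = 0.000624) at 25 mM and by 4.48 at 50 mM, and petD, of the cytochrome complex, by 3.86 and 3.92. Of the 69 plastid-encoded genes 18 were called up and 7 down at either dose, and the list was not called (adjusted p = 0.337 and 0.0507). It reached 0.00642 at 25 mM without the 25 mM solvent array, and at 50 mM between 0.00544 and 0.0423 without solvent control 1, BL replicate 1 or 2 at 0 mM, either array at 1 or 25 mM, or the 50 mM solvent array. The mean 3' to 5' difference of the control probe sets was 0.522 and 0.538, against 0.324 at 0 mM. EXPA16 changed by -2.53 and -3.71. GSTU25 rose by 5.87 and 4.81, CML37 by 4.39 and 3.65, UGT73B4 by 5.00 and 4.40, and the cytochrome P450 gene CYP71B36 by 2.37 and 1.47. Each of these calls held without any single array, except CYP71B36 at 50 mM, which had an adjusted p of 0.0547 without the 50 mM BL array. HSP26.5 rose by 4.02 and 3.88, the latter lost without the 50 mM solvent array (adjusted p = 0.0628). At 25 mM 4 heat shock genes were called, or 6 adjusted over the list alone, and at 50 mM 3, or 5. The list medians were 1.62 (adjusted p = 0.000527, and 0.422 with an estimated correlation) and 1.45 (0.00326, and 0.534). UDP-glycosyltransferases had 9 up and 1 down at 25 mM (adjusted p = 0.00533, and 0.0320 with an estimated correlation) and 9 up and 1 down at 50 mM (0.0107, and 0.0450), and without solvent control 3 the list reached only 0.0546 and 0.0778. Glutathione S-transferases were called up with medians of 0.50 (adjusted p = 0.0161, and 0.326 with an estimated correlation) and 0.53 (0.0282, and 0.397), calls lost without solvent control 3 (0.134 and 0.195), and the first median was 0.32 without the 25 mM solvent array. For H2O2 25 mM against 0 mM, 2083 probe sets were called, 1076 up and 1007 down, with 931 at a log2 change of at least 1, 4090 with the first replicates only, 4928 when solvent control 3 was left out, 776 without the 25 mM solvent array and 300 without the 25 mM BL array. For H2O2 50 mM against 0 mM, 1903 were called, 973 up and 930 down, with 865, 3916, 4584, 501 and 314 under the matching settings.

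The highest dose raised single plastid-encoded genes, AT5G05220 and GSTU25, and lowered the expansin gene EXPA16 and single peroxidase genes. rps14 went from 5.43 ± 0.94 (SD, n = 6) at 0 mM to a mean of 10.97 at 100 mM, and petD, the RNA polymerase gene rpoB and petN rose with it. GSTU25, UGT73B4, CML37 and LTI30 were still raised. The peroxidase gene AT4G26010 went from 7.75 ± 0.62 (SD, n = 6) to 2.98, and EXPA16, the lipase-type gene AT1G75880, AT5G25840 and AT3G62820 fell too. Lectin genes AT1G52060 and AT1G52070 and the peroxidase genes AT1G34510 and AT1G30870 were among the 10 largest falls.

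The comparison of 100 mM with 0 mM asked what the strongest stress does. rps14 rose by a log2 of 5.54 (SE 0.59, adjusted p = 0.000191), AT5G05220 by 4.76 (SE 0.18, adjusted p = 1.50e-07), petD by 4.60, rpoB by 4.03 and petN by 3.67 (SE 0.43, adjusted p = 0.000353). GSTU25 rose 23.0-fold, by 4.52 (SE 0.16, adjusted p = 9.20e-08), UGT73B4 by 4.14, CML37 by 3.63, GT72B1 by 3.36, CYP71B36 by 2.15 and LTI30 by 1.91. AT4G26010 fell by 4.77 (SE 0.51, adjusted p = 0.000187), AT1G75880 fell by 4.04, EXPA16 fell by 3.66 (SE 0.38, adjusted p = 0.00017), and AT5G25840 and AT3G62820 changed by -3.29 and -3.16. None of these calls was lost when any single array was left out. The glutaredoxin gene AT3G62950 rose by 4.18 (adjusted p = 0.00683, and 0.0839 and 0.0825 without the 100 mM solvent or BL array). AT1G34510 fell by 3.94 and AT1G30870 fell as well, with adjusted p of 0.149 and 0.124 without the solvent array and 0.156 and 0.135 without the BL array. AT1G52060 fell by 3.42 (0.113 without the BL array) and AT1G52070 fell by 3.17 (0.0529 and 0.0615 without the solvent or BL array). HSP26.5 rose by 3.71 and FES1A by 1.46, with adjusted p of 0.102 and 0.316 without the 100 mM solvent array.

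Of 69 plastid-encoded genes, 20 were called up and 8 down at 100 mM, with a median log2 change of 0.27 and a mean of 0.74 (camera adjusted p = 0.00961, and 0.639 with an estimated correlation). That call was lost without solvent control 3 (median 0.12, adjusted p = 0.118) or the 100 mM BL array (0.113), and the median was 0.16 without BL replicate 3 at 0 mM. At the same dose the mean difference between 3' and 5' control probe sets was 0.666 ± 0.164 (SD, n = 2) against 0.324 ± 0.115 (SD, n = 6) at 0 mM. The protocol primes at poly(A) tails, and whether the plastid-encoded changes follow the labelling was not tested. The UDP-glycosyltransferases had 9 genes up and 1 down (adjusted p = 0.00961, and 0.0528 with an estimated correlation), with a median of 0.23 that was 0.13 without the 100 mM solvent array and 0.39 without the BL array. The heat shock list had 3 genes called, or 4 adjusted over the list alone, with a median of 0.90 (adjusted p = 0.0307, and 0.868 with an estimated correlation). Its p was 0.0699 without solvent control 1, 0.0723 without solvent control 2, 0.0506 without solvent control 3 and 0.426 without the 100 mM solvent array, and its median was 1.38 without the 100 mM BL array. Detoxification had a median of 1.02 (adjusted p = 0.0167, and 0.174 with an estimated correlation) and the abscisic acid list was called up as well (0.0254, and 0.228), at 0.0506 and 0.0663 without solvent control 3. For H2O2 100 mM against 0 mM, 2037 probe sets were called, 1083 up and 954 down, with 894 at a log2 change of at least 1, 4089 with the first replicates only, 5034 when solvent control 3 was left out, 435 without the 100 mM solvent array and 574 without the 100 mM BL array.

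**Figure D2:**
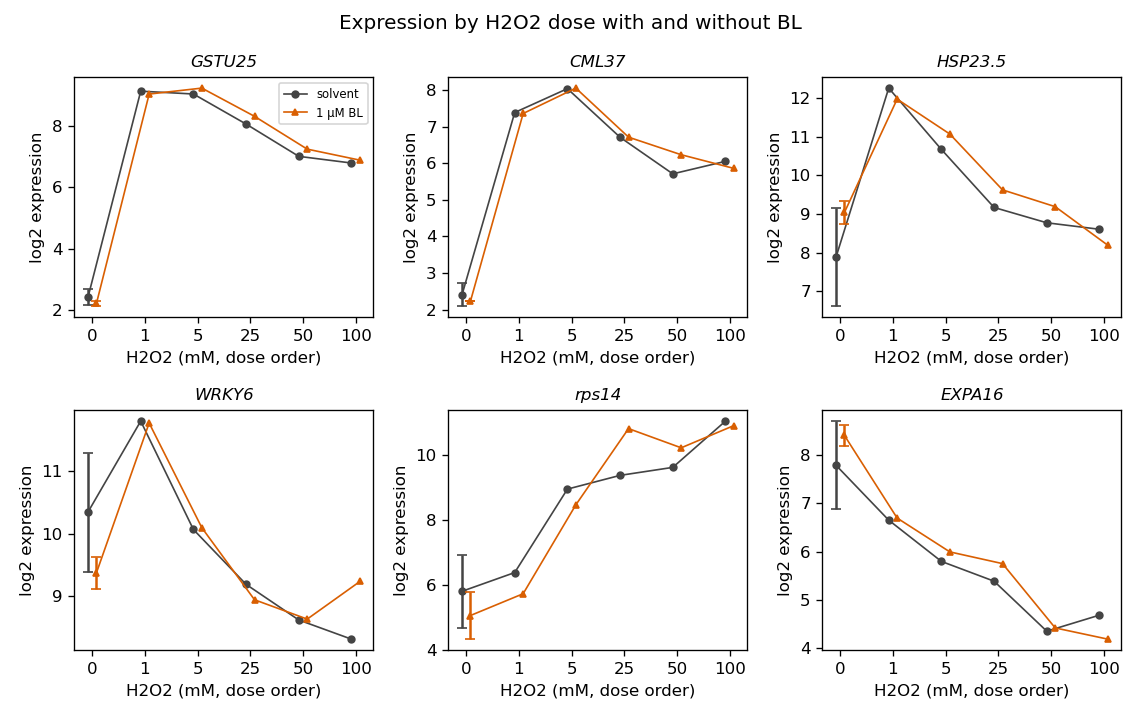
Log2 GCRMA signal (y axis) of GSTU25, CML37, HSP23.5, WRKY6, rps14 and EXPA16 against the H2O2 dose in its order, not to scale (x axis), with BL and with solvent. Points at 0 mM are means of 3 arrays with SD bars, and points above 0 mM are single arrays. GSTU25 rises to a mean of 9.09 at 1 mM and is at 6.84 at 100 mM, while rps14 climbs to 10.97.

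The slope from 1 to 100 mM, added after the data were seen, asked which genes move with dose once H2O2 is present. As a list, heat shock genes were highest at 1 mM and fell with dose, while single plastid-encoded genes such as rps14 rose. HSP23.5 went from a mean of 12.11 at 1 mM to 8.40 at 100 mM, next to 8.47 ± 1.04 (SD, n = 6) at 0 mM. The protein phosphatase gene AT1G07160 went from 7.37 to 3.12, next to 3.04 ± 1.36 (SD, n = 6) at 0 mM. WRKY6, ZAT10, BZIP60, GSTU25 and CML37 also fell with dose, as did the ERF-type transcription factor gene AT1G22810. PYK10, a root glucosidase gene, rose.

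Over that range HSP23.5 fell by 3.70 (SE 0.20, limma adjusted p = 2.72e-06), HSP15.7 and HSP22 changed by -2.96 and -2.84, and FES1A fell as well. AT1G07160 fell by 4.76 (SE 0.45, adjusted p = 3.52e-05), AT1G22810 fell by 4.02 and WRKY6 fell by 3.05 (SE 0.37, adjusted p = 0.000165). GSTU25 fell by 2.48, and CML37, ZAT10 and BZIP60 changed by -1.91, -1.82 and -1.61. UGT73B5 fell by 2.50 and EXPA16 fell by 2.30. rps14 rose by 4.44 (SE 0.57, adjusted p = 0.000231), petD by 4.06, rpoB by 3.54, psbN by 3.00 and PYK10 by 0.94 (SE 0.09, adjusted p = 4.64e-05). These calls held without any single array. All 10 heat shock genes were called down, with a median of -2.48 (camera adjusted p = 3.14e-11, and 0.161 with an estimated correlation), and 10 when adjusted over the list alone. The oxidative stress transcription factors had 2 of 3 down and a median of -1.82 (adjusted p = 0.0241, and 0.161 with an estimated correlation). Both list calls held without any single array. Plastid-encoded genes had 27 up and 13 down (adjusted p = 0.187, and 0.00621 without the 1 mM solvent array), while the 3' to 5' difference of control probe sets went from 0.392 to 0.666, and UDP-glycosyltransferases 6 up and 11 down (0.187). The H2O2 dose slope from 1 to 100 mM called 5048 probe sets, 2919 up and 2129 down, with 1350 at a log2 change of at least 1, 3306 on a linear dose scale, and between 3865 and 4916 when 1 array was left out. Over the same doses the hybridization controls went from 10.6 to 11.4 and the spiked polyadenylated controls from 6.77 to 7.54. Whether this count follows such a trend between arrays was not tested.

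**Figure D3:**
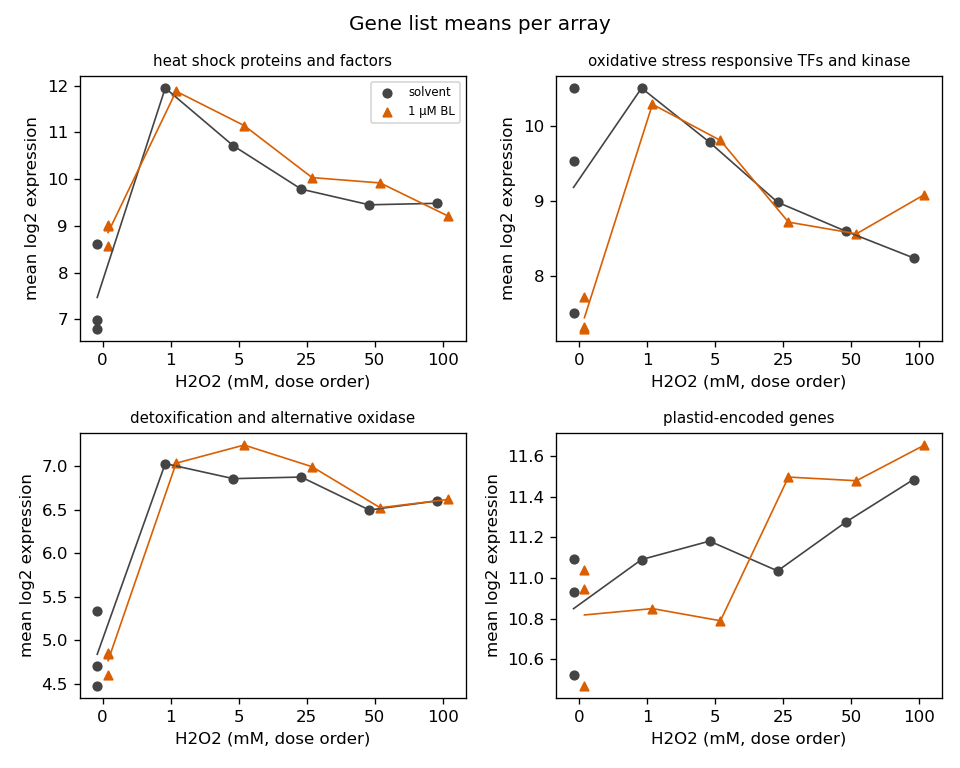
Mean log2 GCRMA signal (y axis) of the heat shock, oxidative stress transcription factor, detoxification and plastid-encoded lists against H2O2 dose in its order, not to scale (x axis), with BL and with solvent. Points are arrays and lines join group means. The heat shock list stands at 11.9 on both 1 mM arrays and at 9.48 and 9.21 on the solvent and BL arrays at 100 mM.

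The planned slopes over all doses, 0 mM included, picked out the plastid-encoded genes rps14 and petD as rises and AT4G26010, EXPA16 and AT1G75880 as falls, with and without BL. Without BL, rps14 rose by 4.99 over the range, petD by 4.18 and rpoB by 3.37, and AT4G26010, EXPA16 and AT1G75880 changed by -4.37, -3.33 and -3.15. With BL, rps14 rose by 6.38, petD by 5.54, ndhF by 4.44 and petN by 4.33, and AT4G26010, AT1G75880 and EXPA16 changed by -5.26, -4.75 and -4.07. AT5G02540 fell by 2.97 without BL (SE 0.20, adjusted p = 5.89e-06). FMA, the gene of a transcription factor of stomatal guard cells, fell by 2.64 without BL (adjusted p = 0.00547, and 0.0635 without the 100 mM solvent array). UGT85A2 rose by 2.49 with BL (SE 0.42, adjusted p = 0.00312).

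The model asked whether expression follows the dose and whether BL changes that. The H2O2 dose slope without BL called 688 probe sets, 443 up and 245 down, and the H2O2 dose slope with BL 1303, 628 up and 675 down. On a linear dose scale the counts were 0 by limma (1482 at an unadjusted p under 0.05) and 10, with the first replicates only 442 and 595, and from 1 to 100 mM 2591 and 2525. The slope without BL gave 83 on the arrays of its own BL state, and the slope with BL 839 at a log2 change of at least 1. Without BL the count was 248 when solvent control 1 was left out, 1204 without solvent control 2, and 302, 295 and 246 without the solvent array at 25, 50 or 100 mM. With BL it was 2346 without solvent control 3, 503, 757 and 587 without BL replicate 1, 2 or 3 at 0 mM, and 628 and 652 without the BL array at 25 or 50 mM. The difference of both slopes gave 0 calls with limma, the tool used for it throughout, with 477 probe sets at an unadjusted p under 0.05 and a smallest adjusted p of 0.803. These 477 are fewer than the share of 0.05 of 13140 that is due with no effect at all. The fit's spread includes solvent control 3, so 0 calls do not show that the slopes are equal. Recovery of simulated slope differences was 14% for a log2 of 1 and 64% for 2, with noise equal on all arrays. No fixed list was called for either slope, and the heat shock list had a median of 1.49 without BL (adjusted p = 0.258) and of -0.06 with BL, where its mean was 0.31 (0.738). Without the 1 mM solvent array, the slope without BL reached 0.0374 for the heat shock list and 0.0425 for the abscisic acid list, and over all arrays these lists had an adjusted p of 0.811 and 0.637 with an estimated correlation. Of the added lists, none was called for the slope without BL, where plastid-encoded genes had 17 up and 6 down (adjusted p = 0.192). With BL, plastid-encoded genes were called up, 20 up and 5 down (adjusted p = 6.17e-05, and 0.466 with an estimated correlation). Over the same doses the 3' to 5' difference of control probe sets went from 0.324 at 0 mM to 0.666 at 100 mM, and the spiked polyadenylated controls from 6.54 to 7.54. Mitochondria-encoded genes were called up too, 10 of 11 higher and 1 called (0.0312, and 0.466), and expansins were called down, 2 of 4 called (0.0312, and 0.393). Without the 100 mM BL array these calls were lost (adjusted p = 0.318 and 0.155), as was the mitochondrial one without BL replicate 3 at 0 mM (0.0821) or the 1 mM BL array (0.0584). For the difference of slopes the plastid-encoded list was called up (adjusted p = 8.49e-07, and 0.421 with an estimated correlation), with 57 of 69 members higher and 0 called, and a median of 0.18 that was 0.071 without solvent control 1, 0.45 without solvent control 3, 0.28 and 0.31 without BL replicate 1 or 2 at 0 mM and 0.080 without the 100 mM BL array. Mitochondria-encoded genes (11 of 11 higher, adjusted p = 0.0150, and 0.421) and WRKY factors (4 of 5 higher, 0.0150, and 0.340) were called up as well, and expansins down (4 of 4 lower, 0.020, and 0.340). These differences lean on single arrays. At 0 mM the mitochondria-encoded list averaged 7.04, 6.47 and 8.44 in solvent controls 1 to 3 and 7.45, 7.21 and 6.79 with BL, and without solvent control 3 its median difference went from 0.49 to -0.089 (adjusted p = 0.655), against 0.75 without solvent control 2. WRKY factors averaged 9.21, 7.95 and 9.81 against 8.24, 8.13 and 7.87, and expansins 5.67, 5.89 and 4.68 against 6.27, 5.89 and 6.09, the latter reaching 0.083 without solvent control 3 and 0.0538 without the 100 mM solvent array. Without the 100 mM BL array the adjusted p was 0.313 for the mitochondrial list and 0.129 for WRKY factors and expansins.

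BL alone changed few genes past the threshold. The chaperone gene AT1G71000, which encodes a DnaJ-domain protein, went from 3.64 ± 0.48 (SD, n = 3) in solvent to 7.26 ± 0.15 (SD, n = 3) with BL. A pair of unnamed probe sets rose with it from close to the floor. Heat shock genes had higher means with BL in 10 of 10 cases, and the oxidative stress transcription factors WRKY53, ZAT10 and WRKY6 had lower means in 3 of 3, although no member of either list was called. As a mean of the list, heat shock genes lay at 6.99, 6.79 and 8.62 in solvent controls 1 to 3 and 8.56, 9.03 and 8.99 with BL, so solvent control 3 lay among the BL arrays and the rise rests on solvent controls 1 and 2. The mean of the transcription factors was 9.54, 7.52 and 10.5 in solvent controls 1 to 3 and 7.73, 7.30 and 7.32 with BL, so solvent control 2 lay among the BL arrays.

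This comparison asked what the hormone does without stress. AT1G71000 rose by a log2 of 3.62 (SE 0.27, limma adjusted p = 0.0426), 12.3-fold, and the unnamed probe sets by 4.23 and 3.74 (adjusted p = 0.0204 for both). These 3 rises were all the calls for BL against solvent without H2O2, with 1213 probe sets at an unadjusted p under 0.05. A fit over all 16 arrays called 100, 57 up and 43 down, while 0 were called with a filter at 7, with trend and robust, or with an equal-variance test (879, 1181 and 1037 at an unadjusted p under 0.05). Leaving out solvent control 2 gave 93 calls and leaving out solvent control 3 gave 52, while 0 remained without solvent control 1 or BL replicate 1 or 3. The AT1G71000 call was lost without solvent control 1 (adjusted p = 0.287) and without BL replicate 1 (0.432), 2 (0.518) or 3 (0.570). The heat shock list had a median change of 1.36 (adjusted p = 0.000195, and 0.643 with an estimated correlation), or 0.88 without solvent control 2 (0.0483). The oxidative stress transcription factors had a median of -1.65 (adjusted p = 0.0259, and 0.643 with an estimated correlation). It was -2.74 without solvent control 2 and -1.04 without solvent control 3 (adjusted p = 0.0450), turned to 0.070 with solvent controls 1 and 3 both left out (0.696), and the call was lost without solvent control 1 (adjusted p = 0.101) or BL replicate 2 (0.0601). Adjusted over each list alone, 0 members of these lists were called. Cell wall loosening genes had a median of 0.79 (adjusted p = 0.10, and 0.643 with an estimated correlation), reaching 0.0174 without solvent control 3, with 2 of 4 up when adjusted over the list alone.

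In seedlings given H2O2, no gene differed between BL and solvent past the threshold. Of the named genes, AT1G71000 had a mean BL response of 0.20 over the 5 doses, AT4G38050 of -0.08 and UGT85A2 of -0.08. The heat shock list had a median of 0.14, higher with BL in 10 of 10 members (camera adjusted p = 0.192). The comparison asked for a BL response under stress, and limma called 0 probe sets, with 122 at an unadjusted p under 0.05, a smallest adjusted p of 1.00 and no other tool run. These 122 are fewer than the share of 0.05 of 13140 that is due with no effect at all. The fit's spread also takes in the 0 mM arrays with solvent control 3, while the estimate rests on pairs at the same dose. So 0 calls do not show that BL had no effect. Simulated BL responses of a log2 of 1 were recovered for 80% of probe sets, with noise equal on all arrays. The heat shock list was called without solvent control 3 (adjusted p = 0.0102), without either 1 mM array (0.0316) or without either 100 mM array (0.00763), while over all arrays its adjusted p was 0.841 with an estimated correlation.

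A test of the BL response with H2O2 against that without it called a few genes. AT1G71000 had a BL response of 3.62 at 0 mM and a mean of 0.20 with H2O2. AT4G38050, of a family of nucleobase and ascorbate transporters, had 1.97, not called at 0 mM (adjusted p = 0.169), and -0.08. UGT85A2 had -1.74, not called either, and -0.08. HLL, which encodes a mitochondrial ribosomal protein, had a BL response of 0.67 at 0 mM and of -0.27 with H2O2.

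The difference of the BL responses was -3.42 for AT1G71000 (SE 0.39, limma adjusted p = 0.0107), -2.05 for AT4G38050 (SE 0.23, adjusted p = 0.0107), 1.66 for UGT85A2 (SE 0.19, adjusted p = 0.0107) and -0.94 for HLL (SE 0.13, adjusted p = 0.0447). With 4 unnamed probe sets these made 8 calls, 1 up and 7 down. The count for this Difference of BL responses with minus without H2O2 was 13 without a filter, 2 with a filter at 7, 15 with quantile normalization, 4 with trend and robust, 938 with the first replicates and 2 with 25, 50 and 100 mM only. It was 1786 without solvent control 2, 110 without solvent control 3, 16 without BL replicate 2, 3 without BL replicate 1 or 3 at 0 mM, and 5 without either 100 mM array. AT1G71000 and UGT85A2 had an adjusted p of 0.0515 without BL replicate 1 and 0.0601 without BL replicate 3, and the HLL call was lost without solvent control 1, any BL array at 0 mM or any single H2O2 array (adjusted p from 0.0865 to 0.172). The heat shock list had a lower BL response with H2O2 in 10 of 10 members, with a median difference of -1.23 (camera adjusted p = 0.00323, and 0.643 with an estimated correlation). It reached 0.0805 without solvent control 1 and 0.148 without solvent control 2, its median was -1.85 without solvent control 3, and 4 members were called down when adjusted over the list alone. The oxidative stress transcription factors differed by a median of 1.93 (adjusted p = 0.0344, and 0.619 with an estimated correlation), with 0.0805 without solvent control 1, 0.0727 without BL replicate 2 and a median of 3.03 without solvent control 2, but of 0.067 with solvent controls 1 and 3 both left out, where the call was lost.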

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

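The differences in BL response were planned, while the regroupings of arrays for them and the comparison of control probe sets between doses were tests chosen only after the result was seen. No group had between 4 and 10 arrays, so no single array was tested for lying apart from its group.

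A test of the difference itself called 8 probe sets for a BL response that differed with and without H2O2. The difference was -3.42 for AT1G71000 (adjusted p = 0.0107), -2.05 for AT4G38050 (0.0107), 1.66 for UGT85A2 (0.0107) and -0.94 for HLL (0.0447). The named genes had BL responses of 3.62, 1.97, -1.74 and 0.67 at 0 mM, and of 0.20, -0.08, -0.08 and -0.27 as a mean over the 5 doses. HLL was lower with BL at 5 of 5 doses, while AT1G71000 was higher at 3 of 5 and AT4G38050 and UGT85A2 at 2 of 5. BL and solvent were exchanged within doses and at 0 mM in 100 regroupings drawn from 320, and 13 of them, the real one included, called as many probe sets. The highest of the others called 16 against the real 8, so chance is not excluded for this count. The count was 1786 without solvent control 2, 110 without solvent control 3, 16 without BL replicate 2, 3 without BL replicate 1 or 3, and 5 without either 100 mM array. AT1G71000 and UGT85A2 had an adjusted p of 0.0515 without BL replicate 1 and 0.0601 without BL replicate 3. The HLL call was lost without solvent control 1, any BL array at 0 mM or any single H2O2 array, with an adjusted p from 0.0865 to 0.172.

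The same test picked out 2 gene lists. Heat shock genes had a lower BL response with H2O2 than without in 10 of 10 members, with a median difference of -1.23 (camera adjusted p = 0.00323, and 0.643 with an estimated correlation). Without solvent control 1 that p was 0.0805 and without solvent control 2 it was 0.148, while the median was -1.85 without solvent control 3. The oxidative stress transcription factors had a higher response in 3 of 3 members, with a median difference of 1.93 (adjusted p = 0.0344, and 0.619 with an estimated correlation). Without solvent control 1 that p was 0.0805 and without BL replicate 2 it was 0.0727, while the median was 3.03 without solvent control 2, but 0.067 with solvent controls 1 and 3 both left out, where the call was lost. For the planned comparison of BL with solvent at 0 mM, the 10 splits of the 6 arrays are too few for a share under 0.05: 1 split, the real one, gave as many as its 3 calls and the highest other gave 0. For BL with solvent across the doses, the 16 exchanges decide nothing, since each calls at least the real 0 whatever the data, and they are too few as well. All 16 gave as many as the real 0, with 0 the highest other. Limma put 122 of 13140 probe sets at an unadjusted p under 0.05, fewer than are due with no effect at all.

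Control probe sets, which no comparison uses, were higher at 100 mM than at 0 mM. The hybridization controls averaged 10.7 ± 0.20 (SD, n = 6) at 0 mM and 11.4 ± 0.086 (SD, n = 2) at 100 mM, a difference of 0.694. The spiked polyadenylated controls averaged 6.54 ± 0.30 (SD, n = 6) and 7.54 ± 0.064 (SD, n = 2), a difference of 0.995. At 1, 5, 25 and 50 mM the hybridization controls averaged 10.6, 10.5, 10.99 and 10.9, and the spiked controls 6.77, 6.57, 7.12 and 7.44. The cause was not tested.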

How the results depend on the processing

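The limits to the doses 1 to 100 mM, the slope over that range, the fits without solvent controls 1 and 3, and all alternatives for the added gene lists were tests chosen only after the result was seen, and the other alternatives were planned.

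BL against solvent without H2O2 gave 3 calls. A filter at 7, an eBayes prior with trend and robust, and an equal-variance test per probe set each left 0 with their tool, with 879, 1181 and 1037 probe sets at an unadjusted p under 0.05. The fit over all 16 arrays gave 100 calls, 57 up and 43 down. Without a filter 2 were called, of which 0 were among the 3. Leaving out 1 array gave from 0 (solvent control 1, BL replicate 1 or 3) to 93 (solvent control 2), with 52 without solvent control 3. With solvent controls 1 and 3 both left out there were 31. The cause was not tested.

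With the replicate number as a block, limma called 0 probe sets for BL against solvent without H2O2, with 974 at an unadjusted p under 0.05. Arrays of the same number correlated at 0.183, 0.108 and -0.0657 after removal of the group means, and those of unlike numbers at -0.233 to 0.0756. With 3 arrays per group these values cannot decide whether the numbers pair the arrays. The unblocked fit was the planned main one, so its count of 3 is reported, and it does not hold with the block.

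Asking for a log2 change of at least 1, which lowers a count by construction, gave 1031 calls for H2O2 1 mM against 0 mM, 1190 for H2O2 5 mM against 0 mM, 931 for H2O2 25 mM against 0 mM, 865 for H2O2 50 mM against 0 mM and 894 for H2O2 100 mM against 0 mM. With the first replicates only, which leaves out solvent control 3 among others, the counts were 4755, 5186, 4090, 3916 and 4089, and the cause was not tested. Leaving out 1 array gave from 676 to 5981 calls at 1 mM, 879 to 5984 at 5 mM, 300 to 4928 at 25 mM, 314 to 4584 at 50 mM and 435 to 5034 at 100 mM. Every highest count came without solvent control 3 and every lowest without an array of the dose itself. With solvent controls 1 and 3 both left out the counts were 6728, 6555, 5574, 5282 and 5708.

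The H2O2 dose slope without BL gave 688 calls, against 442 with the first replicates, 0 on a linear dose scale (limma, 1482 at an unadjusted p under 0.05), 83 on the arrays of its own BL state and 2591 from 1 to 100 mM. The H2O2 dose slope with BL gave 1303, against 839 with a log2 change of at least 1, 595 with the first replicates, 10 on a linear scale and 2525 from 1 to 100 mM. Leaving out 1 array gave from 246 (solvent at 100 mM) to 1204 (solvent control 2) without BL, and from 503 (BL replicate 1 at 0 mM) to 2346 (solvent control 3) with BL. With solvent controls 1 and 3 both left out they gave 237 and 2387. The H2O2 dose slope from 1 to 100 mM gave 5048, against 1350 with a log2 change of at least 1 and 3306 on a linear scale. Apart from the minimum change and the smaller fits, the cause was not tested.

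The Difference of BL responses with minus without H2O2 gave 8 calls, against 13 without a filter, 2 with a filter at 7, 15 with quantile normalization, 4 with trend and robust, 938 with the first replicates and 2 with 25, 50 and 100 mM only. Leaving out 1 array gave from 3 (BL replicate 1 or 3 at 0 mM) to 1786 (solvent control 2), and leaving out both solvent controls 1 and 3 gave 83. The cause was not tested. The gene list tests gave 19 calls over the comparisons without the added slope, 0 with the correlation estimated by camera, and 12 without solvent controls 1 and 3. The added lists gave 15, and 4 with the correlation estimated, and the fixed lists for the slope from 1 to 100 mM gave 2, and 0 with the correlation estimated. For these lists the cause was not tested. BL across the doses and the difference of slopes gave 0 with limma in every alternative.

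Directions changed in 19 cases where the main fit or the other setting gave a call. From 1 to 100 mM the slope of AT3G50560 without BL became -0.038 and that of AT1G30870 with BL 0.077. Without a filter the detoxification list had medians of -0.15 at 25 mM and -0.13 at 50 mM, over more members. For BL against solvent without H2O2 the oxidative stress transcription factors had a median of 0.070 with solvent controls 1 and 3 both left out.

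Among the added lists, leaving out 1 array moved the median of the plastid-encoded genes from -0.13 (solvent control 3) to 0.18 for BL against solvent without H2O2, from -0.17 to 0.13 (solvent control 3) for the difference of BL responses, from -0.38 to 0.11 (5 mM BL array) at 5 mM, from -0.11 to 0.063 (25 mM solvent array) at 25 mM, and from -0.074 (either 25 mM array) to 0.12 for BL across the doses. For mitochondria-encoded genes it moved the slope from -0.43 to 0.45 (solvent control 3) without BL and from -0.092 (100 mM BL array) to 0.57 with BL, and the difference of slopes from -0.089 (solvent control 3) to 0.75. For glutathione S-transferases at 1 mM it moved the median from -0.16 to 0.17 (1 mM BL array). With solvent controls 1 and 3 both left out the mitochondria-encoded genes had 0.62 for BL against solvent without H2O2, 0.56 for the slope without BL, -0.28 for the difference of slopes and -0.53 for the difference of BL responses. The cause was not tested.

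Of 6062 other settings for 258 results on named genes, 5268 kept direction and call and 792 lost the call. Of 3791 for 204 list results, 3387 did so, 96 lost and 75 gained a call, and 216 uncalled medians changed sign. Each setting tried gave a value, and where it left a single array that array is assumed to vary like the others. Signal over background limits the folds of genes near the floor of 2.12, such as GSTU25 and CML37 at 0 mM.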

Other observations

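All tests in this part were chosen only after the result was seen, and the explanations by a mix-up of samples and by a shared batch were divided into several after their first values were known.

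Heat shock genes were highest at 1 mM and lower at 100 mM, with a median log2 change of -2.48. A scaling difference that lowers the high-dose arrays is argued against, since the hybridization controls were higher at 100 mM (11.4) than at 1 mM (10.6). After their subtraction the change was -3.20, but subtracting rising controls enlarges any fall, so the added size says nothing about heat shock genes. A loss of 5' ends shared by all transcripts is argued against as well, since the mean 3' to 5' difference of the controls rose by only 0.273, from 0.392 to 0.666. It went from 1.41 to 1.91 for actin, 0.31 to 0.40 for GAPDH and -0.54 to -0.31 for ubiquitin. These controls cannot show a loss particular to heat shock transcripts, which was not tested. Dose labels in reverse order stay open: of 5048 probe sets called for the slope, 2947 (58.4%) had a 0 mM mean nearer to 100 mM, where about all were needed. A weaker heat shock response at the highest doses may be the biological reading, and it cannot be told apart from reversed labels by these values.

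Solvent control 3 stood apart from the 5 other 0 mM arrays, and no biological explanation was tested. An H2O2-treated sample in its place is argued against by its mean correlation with the H2O2 arrays of 0.874, where the lowest of these reached 0.962 (SD 0.00701). H2O2-treated RNA mixed in is argued against as the whole difference, since 1131 probe sets, 640 below and 491 above, lay over a log2 of 1 outside the range of all 15 other arrays, and at most 15 did so on any other array. Some such RNA stays open, since probe sets off at 0 mM and on with H2O2 were 1.09 higher but numbered only 3, and so does degradation, with a 3' to 5' difference 0.0223 above the highest of the others (SD 0.108). A lower share of leaf tissue stays open too. Photosynthesis genes changed by a median of -0.87 and root markers by -2.16. But EXPA7 and EXPA18 averaged only 4.44 and 4.39 on the 5 other 0 mM arrays and lay at the floor in solvent control 3. They lay at the floor on the H2O2 arrays too, at no more than 2.28 and 2.27, so they cannot tell tissue share from an H2O2 response. That leaves PYK10 alone (12.0 against 13.6 ± 0.11, SD, n = 5).

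The H2O2 arrays of every dose stood apart from the 0 mM arrays, the labels give no batches, and H2O2 itself is the biological candidate. A test of a batch of the H2O2 arrays as the whole difference decides nothing: of the 2083 probe sets called at 25 mM, 913 (43.8%) also followed the dose from 1 to 100 mM, but so did 38.4% of all probe sets. A batch shared with solvent control 3 is argued against for GSTU25, which in that array was only 0.31 above the mean of the 5 others and with H2O2 was raised by 4.52 to 6.82 at every dose (SE 0.16). For other genes it stays open. On 238 probe sets all 10 H2O2 arrays lay over 1 apart from the 5 other 0 mM arrays. Solvent control 3 was not shifted for 31 of these (13.0%), between the limits set. For the rest it lay beyond the range of the 5 other 0 mM arrays, towards the H2O2 arrays. Of 4928 probe sets called at 25 mM without solvent control 3, it lay on the H2O2 side of the mean of the 5 others for 73.7%. It lay nearer to the H2O2 arrays for 2903 (58.9%). But its mean correlation with them of 0.874 was below the 0.907 to 0.924 of the other 0 mM arrays, where a shared batch needed a higher one.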
